A study of Rattus norvegicus with 109 samples.

How the data were processed

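RNA of 19 genes was measured in 109 laser-captured sections of the rat NTS on BioMark microfluidic chips with EvaGreen detection and 30 PCR cycles, per the labels' protocols. The labels name the strain, the procedure and an animal number for each section. Cocktail rats received 25 uL of a 1:1 mix of the 2 microRNA inhibitors at 10 uM, per the labels' protocols. Each label was used as given. Its animal numbers make 20 sets of sections from 19 numbers, because rat 4614 is named under both WKY Cocktail and WKY Scrambled. The series' design text speaks of 4 to 5 rats per group. The animal numbers give 4, 5 and 3 rats for WKY Cocktail, Scrambled and Sham, and 5, 2 and 1 for SHR. This conflict could not be resolved, and the animal numbers were followed.

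The deposited table of normalised values is on a log2 scale, as minus ΔCt, with the direction found from the values, since each value plus the raw cycle number (Ct) of the same section is constant over genes. The deposited raw values are Ct, treated here as a score, and ranged from 4.52 to 29.0. How Ct was called and which software version did so is not given in the sources used here. The constant that the authors subtracted in each section equalled the median Ct of the 19 genes in 60 of 109 sections, and was not the Ct of a single reference gene. These were 59 of 59 SHR and 1 of 50 WKY sections, so the constants of the 2 strains are not alike. In WKY it lay on average 0.17 below that median (SD 0.47 over sections), which lowers WKY values by as much against SHR, and by 0.40 in WKY Scrambled. Centring all raw sections on the median, which removes this difference, is one of the alternatives. In 44 sections, all from WKY rats, the normalised values matched the raw values of another section name of the same rat. All 109 normalised sections found their raw section within the same rat, so means per rat were unaffected. Both tables lack the same 160 of 2071 values. Such gaps can be transcripts not detected within the cycle limit or failed reactions, and these cannot be told apart from the tables. A section's median Ct stands for its RNA input here, and a later median leaves low transcripts closer to the detection limit.

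The gene names and transcript identifiers of the tables were matched to a RefSeq gene table for assembly GRCr8, and all 19 matched. The names are printed as in the tables, so EiF4e stands for the gene of the cap-binding factor. The values of 1 of the 19 genes are not reported here, although the gene entered the fits, the adjustment over all genes and over its list, and the profile distances. No genome build is named by the tables, so no coordinates are given, and primer sequences were not used here. The gene lists fixed before the data were examined had measured members for catecholamine genes (Dbh, Th), angiotensin-system genes (Ace, Agtr1a, Agtrap), immediate-early factors (Fos, Jun), inflammatory, leukotriene and prostaglandin genes (Alox5ap, Il10, Il1a, Il1b, Ltb4r, Ptgr1, Ptgs1, Ptgs2), signalling (Rgs4) and reference genes (Actb). EiF4e fell in no list. The other fixed lists, among them glutamate and GABA receptors, ion channels, neuropeptides, growth factors, markers of neurons, astrocytes, microglia, oligodendrocytes and endothelium, and published targets of the 2 microRNAs, had 0 measured members. The cell make-up of the sections can therefore not be compared.

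Normalised values were averaged over the sections of each rat and procedure, leaving out missing values. The 20 means per gene were fitted with limma (version 3.58.1, in R 4.3.3), with the 6 groups as the only factor, so that all groups shared 1 estimate of the spread. Groups of 1 or 2 rats borrow that spread. Contrasts were tested two-sided with Benjamini-Hochberg adjustment over the 19 genes of each comparison and a threshold of 0.05. The 2 sets of rat 4614 entered as separate rats, with leaving them out as an alternative. Mean profiles were compared with exact permutation tests of the rats' labels on the Euclidean distance, over the genes with a value in every rat compared. The variance between and within rats came from mixed models (lme4 1.1.37). Shares of sections with a missing value were tested for genes with over 10% missing. Full statistics were given for genes that passed (10 at most), or for the 5 genes with the smallest p where fewer passed, as fixed before the data were examined. Figures were drawn with matplotlib 3.10.9.

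The code was tested on simulated data, 200 draws per comparison with 4 of 19 genes changed. For SHR Cocktail against Scrambled, 5.38% of changes of 1 on the log2 scale were recovered, 35.8% of changes of 2 and 84.0% of changes of 4, with at most 1.13% of unchanged genes called. For SHR against WKY under Cocktail, 55.9% of changes of 2 and 91.4% of changes of 4 were recovered. The draws were independent between genes and gave each gene the same spread in every rat. The SHR Scrambled rats were unlike this, with a Fos SD of 3.21 against 0.44 in SHR Cocktail. These rates are therefore not the error rates of the comparisons with SHR Scrambled.

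Alternatives fixed before the data were examined were raw Ct centred on the section median, raw Ct with no normalisation, missing values set at the gene's lowest value, filters on genes and on sections, medians in place of means, weights by the number of sections, leaving out rats with 1 section or rat 4614, sections as replicates with the rat as a random block or with no block, the section number as a block, fits of the compared groups alone, exact permutation in place of limma, and leaving out each rat in turn. Leaving out sections with a median Ct over 18, Actb as the reference and the section median Ct as a covariate were added after the data had been seen. Late sections were picked by their name in the raw values. As most WKY names differ between raw and normalised values, this setting left most late normalised values in. No chip, plate or run was named for the sections, so no fit with a batch could be made.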

Results

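Transcript levels of 19 genes were measured by quantitative PCR in 109 laser-captured sections of the nucleus of the solitary tract (NTS), the brainstem region that receives signals from the baroreceptors. The sections came from spontaneously hypertensive rats (SHR) and from Wistar Kyoto rats (WKY), their normotensive comparison strain. Each strain received 1 of 3 procedures. "Cocktail" was a mix of locked nucleic acid inhibitors of miR-135a and miR-376a, "Scrambled" was a locked nucleic acid with no intended target, and "Sham" was surgery with an empty needle. By the animal numbers in the labels, WKY contributed 27 Cocktail sections from 4 rats, 15 Scrambled sections from 5 rats and 8 Sham sections from 3 rats. SHR contributed 17 Cocktail sections from 5 rats, 15 Scrambled sections from 2 rats (14 from rat 4600 and 1 from rat 4604) and 27 Sham sections from 1 rat. The SHR Cocktail rats held 4 (rat 1694), 2 (rat 1696), 9 (rat 4595), 1 (rat 4598) and 1 (rat 4602) sections. Every rat had the same weight in the main fit, whatever its number of sections. The rat was the replicate throughout, so n counts rats. Values are normalised cycle numbers on a log2 scale, where a higher value means more RNA, and folds assume a doubling of product per cycle. The median cycle number of a section lay between 10.8 and 23.1, and 9 sections, all from WKY rats, had a median above 18. Sections of 1 rat varied more than rats of 1 group did, with median standard deviations over genes of 1.42 and 0.56 on the log2 scale.

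The first question was which NTS transcripts differed after inhibition of the 2 microRNAs in the hypertensive strain. In SHR, Agtr1a, which encodes the receptor for most central actions of angiotensin II, was 5.33-fold higher after Cocktail than after Scrambled. Its level was -4.55 ± 1.01 (SD, n = 5) after Cocktail and -6.96 ± 0.69 (SD, n = 2) after Scrambled, a log2 fold change of 2.41 with a standard error of 0.704 (limma, adjusted p = 0.0331). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was at -5.19 ± 0.75 (SD, n = 4) after Cocktail and at -1.15 in rat 4600, the only Scrambled rat with a Ptgs2 value. This log2 fold change of -4.04 (standard error 1.17, limma, adjusted p = 0.0331) thus sets 4 rats against 1 rat that is assumed to vary like the others, and rat 4600 was also the highest SHR rat for Fos, Il1a and Il1b. It was the lowest SHR rat for Agtr1a (-7.45, from 6 of its 14 sections), Dbh (-7.70), Th (-1.27), Ace (-0.57), Agtrap (0.53), Ptgr1 (-1.85) and Ptgs1 (-2.67), so that the Agtr1a call rests in part on the same rat. With missing values set at the gene's lowest value, the fold change of Ptgs2 was -0.79 (adjusted p = 0.825).

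By gene group, 1 of the 3 angiotensin-system genes reported here was higher after Cocktail in SHR (Agtr1a), and Ace, which makes angiotensin II, and Agtrap did not pass. Of the 8 inflammatory, leukotriene and prostaglandin genes, 1 passed (Ptgs2, lower on the single Scrambled rat with a value), and 7 did not pass. Both counts were the same when p-values were adjusted over the list alone. Rgs4, a regulator of G protein signalling, had a log2 fold change of 2.31 with a standard error of 0.816 (adjusted p = 0.0723). Fos, an immediate-early transcription factor of activated neurons, had -2.41 with a standard error of 0.935 (adjusted p = 0.0921). Adjusted over the list alone, Fos passed in its list of 2 genes, and Rgs4 is the only measured gene of its list, so that its p stays unadjusted there. Dbh, which converts dopamine to noradrenaline, had 2.80 with a standard error of 1.31 (adjusted p = 0.175). Th, the first enzyme of catecholamine synthesis, had 1.98 with a standard error of 1.40 (adjusted p = 0.332). Fos was at 4.69 in rat 4600 and at 0.15 in rat 4604, so the Scrambled mean of 2.42 lay between 2 very unlike rats. Without rat 4604, which leaves rat 4600 as the only Scrambled rat, Fos, Dbh and Th also passed, and without rat 4600 Fos was at -0.14 (adjusted p = 0.973) and Dbh at 0.75 (adjusted p = 0.952).

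In all, 2 of 19 genes passed in SHR, of which Ptgs2 did so against a single Scrambled rat with no spread of its own and Agtr1a against 2 rats, and 5 had an unadjusted p under 0.05. No gene passed without Scrambled rat 4600 or without any 1 of Cocktail rats 1694, 1696, 4598 and 4602. The call of Agtr1a was thus lost in 5 of 7 fits that left out 1 rat, with a log2 fold change of 1.93 (limma, adjusted p = 0.282) without rat 4600, and in 7 of 15 other settings, and without rat 4600 Ptgs2 could not be compared. An exact permutation test of rats called 0 genes, and it can go no lower than p = 0.0476 for 5 against 2 rats before adjustment. The distance between the mean profiles over 17 genes was 5.92 (exact permutation p = 0.0952). Ptgs2 and Il1b, which lacked a value in some of these rats, were left out of it.

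**Figure D1:**
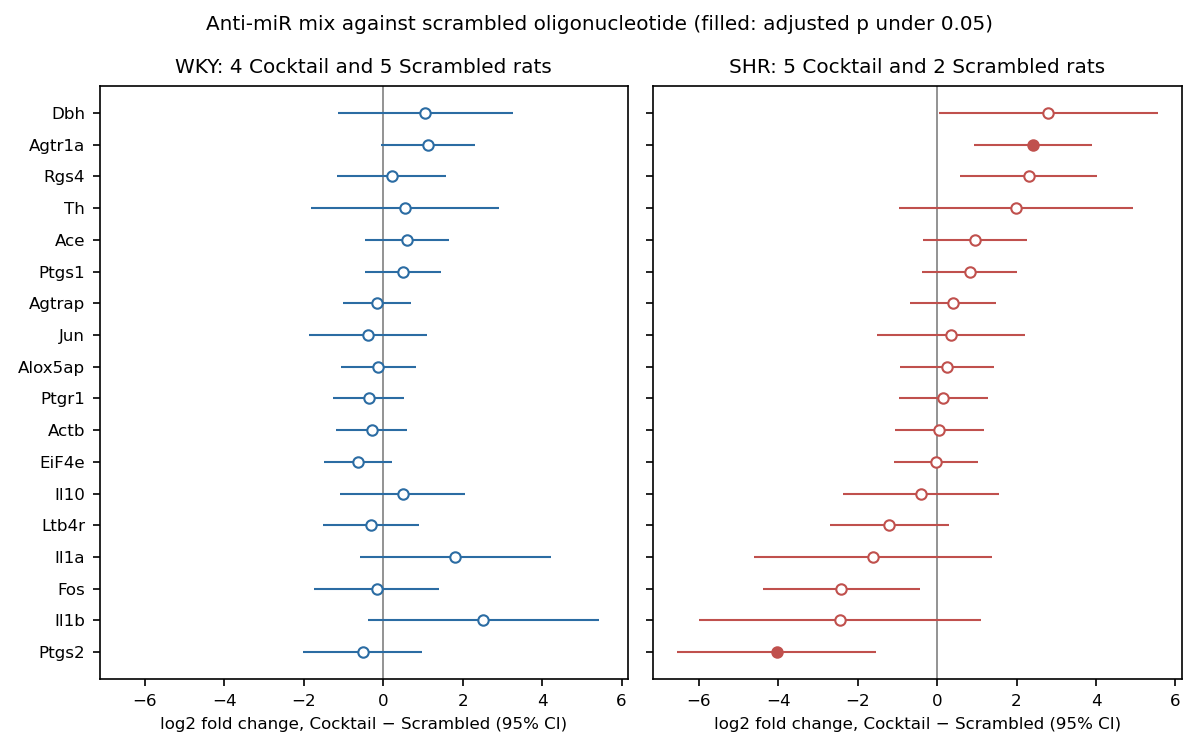
Log2 fold change of Cocktail over Scrambled (x axis) for each of 18 genes (y axis), in WKY (left, blue) and SHR (right, red); points are limma estimates, lines are 95% confidence intervals and filled points have an adjusted p under 0.05. The filled points are Agtr1a at 2.41 and Ptgs2 at -4.04, both in SHR, where Ptgs2 compares 4 Cocktail rats with 1 Scrambled rat.

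The same comparison in WKY asked whether the inhibitors changed these transcripts in normotensive rats. No gene passed in WKY. Agtr1a was at -1.46 ± 0.51 (SD, n = 4) after Cocktail and at -2.59 ± 1.03 (SD, n = 5) after Scrambled, a log2 fold change of 1.13 with a standard error of 0.565 (limma, adjusted p = 0.631). The interleukin genes Il1b and Il1a, which encode pro-inflammatory cytokines, had log2 fold changes of 2.52 (standard error 1.36) and 1.82 (standard error 1.14), each with an adjusted p of 0.631. EiF4e, the cap-binding translation factor, had -0.64 (standard error 0.405, adjusted p = 0.631) and Ace had 0.61 (standard error 0.502, adjusted p = 0.860). Without the Cocktail set of rat 4614, Il1b was at 1.35, while Ace rose to 1.02. Without the Scrambled set of that number, Il1a was at 0.85 and EiF4e at -0.35. Ptgs2 differed by -0.51 with a 95% confidence interval from -2.01 to 0.99. None of the 2 catecholamine, 3 angiotensin-system, 2 immediate-early and 8 inflammatory genes reported here passed, over all genes or adjusted over the list alone.

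Limma thus called 0 of 19 genes in WKY, 0 had an unadjusted p under 0.05, and an exact permutation test of rats also called 0. The mean profiles over 18 genes, without Il1b, lay 2.85 apart, against a median of 3.11 over all ways to divide the rats (exact permutation p = 0.627). Simulations of this comparison changed 4 of 19 genes and gave each gene the same spread in every rat. In these, 11.6% of changes of 1 on the log2 scale were recovered, 60.4% of changes of 2 and 91.8% of changes of 4.

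The difference between the strains in their response to Cocktail was tested directly. Ptgs2 had a difference of -3.53 on the log2 scale between the SHR and the WKY response (standard error 1.37), which did not pass (limma, adjusted p = 0.298) and turned to 0.62 with missing values at the lowest value. Il1b had a difference of -4.96 (standard error 2.16), Rgs4 of 2.09 (standard error 1.05), Il1a of -3.43 (standard error 1.82) and Fos of -2.24 (standard error 1.20), each with the same adjusted p of 0.298. Agtr1a had a difference of 1.29, with a 95% confidence interval from -0.62 to 3.19. Limma called 0 of 19 genes in this test, and 2 had an unadjusted p under 0.05 (Ptgs2 and Il1b). Leaving out either Scrambled rat of SHR leaves 1 rat there. Without rat 4604, which has 1 section, the difference was -4.51 for Fos, -7.65 for Il1b and -5.69 for Il1a. Without rat 4600 it was 0.03 for Fos, -2.27 for Il1b and -1.17 for Il1a. The Rgs4 difference went the other way, to 1.63 without rat 4604 and 2.56 without rat 4600.

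**Figure D2:**
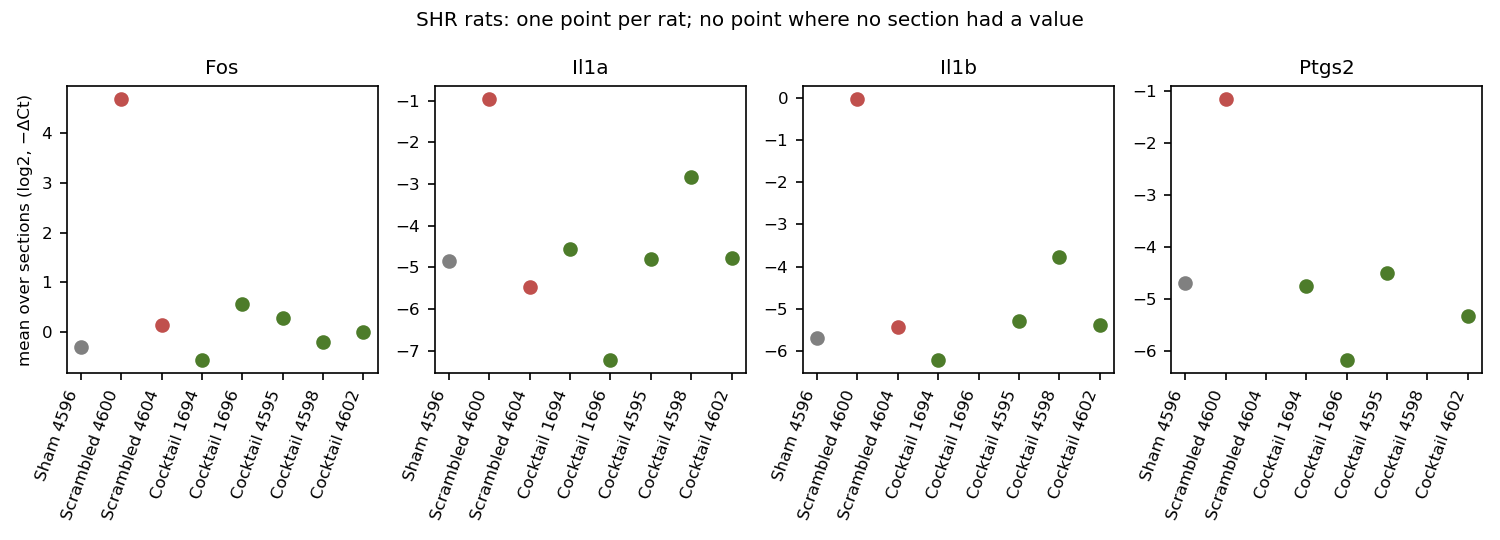
Mean normalised expression (y axis, log2, minus ΔCt) of Fos, Il1a, Il1b and Ptgs2 in each SHR rat (x axis: Sham in grey, Scrambled in red, Cocktail in green, with the animal number); each point is 1 rat's mean over its sections, with no point where no section had a value. Rat 4600 is highest for all 4 genes, with Fos at 4.69 and Ptgs2 at -1.15.

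The strains were then compared under each procedure, which asks how the NTS of the hypertensive strain differs from that of its control. Alox5ap, which presents arachidonic acid to the lipoxygenase of leukotriene synthesis, was far higher in SHR. Ace, Agtr1a, the transcription factor Jun, Rgs4 and the anti-inflammatory cytokine Il10 were lower. Under Cocktail, where SHR and WKY had 5 and 4 rats, Alox5ap was at 1.19 ± 0.92 (SD, n = 5) in SHR and -3.25 ± 0.31 (SD, n = 4) in WKY, a 21.8-fold difference (limma, adjusted p = 2.73e-07). Jun was 18.8-fold lower in SHR (log2 fold change -4.23, standard error 0.708, adjusted p = 8.35e-05). Ace was 9.53-fold lower (-3.25, standard error 0.502, adjusted p = 4.70e-05), and Agtr1a was 8.52-fold lower (-3.09, standard error 0.565, adjusted p = 0.000176).

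Under Cocktail, 7 of 19 genes differed between the strains, 2 higher and 5 lower in SHR. Of the 3 angiotensin-system genes reported here, which are not the whole list, 2 were lower (Ace and Agtr1a). Agtrap, the gene of a protein that binds the angiotensin receptor, was higher. Agtrap had a log2 fold change of 1.10 (standard error 0.409, adjusted p = 0.0424), and its call was lost in 6 of 9 fits that left out 1 rat (WKY 4612 or 4614, SHR 1694, 4595, 4598 or 4602) and in 7 of 16 other settings. Of the 8 inflammatory genes, Alox5ap was higher, Il10 was lower by -2.22 (standard error 0.745, adjusted p = 0.0263), and 6 did not pass, among them Ltb4r (-0.17), Ptgr1 (0.02) and Ptgs1 (-0.50). Rgs4 was lower by -2.41 (standard error 0.654, adjusted p = 0.00674). Neither catecholamine gene passed, with Dbh at -2.30 (adjusted p = 0.0879) and Th at -0.23 (adjusted p = 0.887), and Fos was at 1.00 (adjusted p = 0.365). The exact permutation test of rats called 10 genes, among them all 7 called by limma as well as Dbh (adjusted p = 0.0335) and Fos (adjusted p = 0.0452). Actb, a common reference transcript, differed by -0.23 (standard error 0.427, adjusted p = 0.760).

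**Figure D3:**
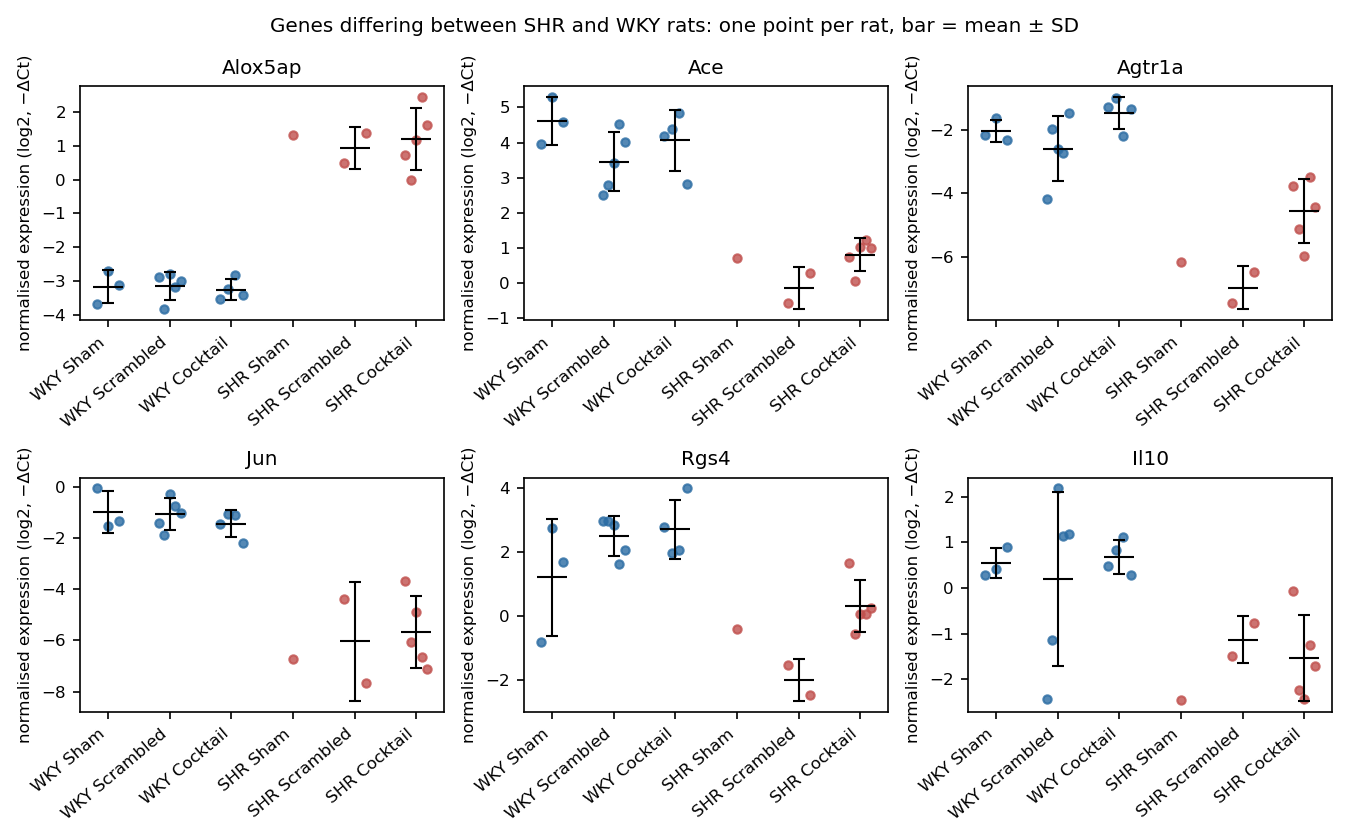
Normalised expression (y axis, log2, minus ΔCt) of 6 genes in the 3 WKY (blue) and 3 SHR (red) groups; each point is the mean over the sections of 1 rat, and horizontal bars with whiskers are the mean ± SD of groups with more than 1 rat. All SHR rats lie above all WKY rats for Alox5ap (lowest SHR -0.01, highest WKY -2.69) and below them for Ace and Jun.

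Over the control procedures, taken as the mean of Scrambled and Sham in each strain, 9 genes differed, 3 higher and 6 lower in SHR. SHR had 2 Scrambled rats and 1 Sham rat here, and WKY had 5 and 3. The only SHR Sham rat weighs as much as the 2 Scrambled rats together and is assumed to vary like the others. Alox5ap was again higher, by 4.27 on the log2 scale (standard error 0.479, limma, adjusted p = 1.19e-06). Jun (-5.35, standard error 0.752), Agtr1a (-4.25, standard error 0.600) and Ace (-3.75, standard error 0.534) were lower, each with an adjusted p of 8.17e-06. Rgs4 was lower by -3.06 (adjusted p = 0.00140), Dbh by -3.72 (adjusted p = 0.0117) and Il10 by -2.16 (adjusted p = 0.0331). Il1b was higher by 4.55 (adjusted p = 0.0135) and Fos by 2.11 (adjusted p = 0.0355). Fos, Dbh, Il10 and Il1b did not pass without rat 4600, which left 5 genes. The call of Fos was lost in 5 of 10 fits that left out 1 rat (SHR 4600, WKY 1700, 4610, 4611 or 4617) and in 5 of 15 other settings, and that of Il10 in 2 of 10 (SHR 4600 or WKY 4617) and in 6 of 15.

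Ace, Agtr1a, Alox5ap, Il10, Jun and Rgs4 passed in both strain comparisons with the same direction. These are 6 genes, 1 higher and 5 lower, where independent lists of these lengths would share 0.316 higher and 1.58 lower. The 2 lists are not independent, since 1 fit gave both with the same spread per gene. A run that differed by strain would also appear in both, so the overlap is no separate support. All 8 SHR rats lay above all 12 WKY profiles for Alox5ap, and below them for Ace and Jun. For 1 gene, 0.00159% of the ways to label the profiles separate them so completely. The call of Il10 was the least stable of the 6. Under Cocktail it was lost without WKY rat 4607 or 4612 or SHR rat 4595 or 4602, and its fold change was -0.96 (adjusted p = 0.466) with missing values at the lowest value. Without any normalisation, Alox5ap passed in both comparisons, and Ace, Agtr1a, Jun and Rgs4 passed over the controls and not under Cocktail. The value that the authors subtracted was the median of the 19 genes in 59 of 59 SHR sections and in 1 of 50 WKY sections, and all 6 genes kept call and direction when every section was centred on that median. No chip or run was given for the sections, so strain and run cannot be told apart.

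Within the Scrambled groups, with 2 SHR and 5 WKY rats, 8 genes differed. Alox5ap was higher by 4.07 (standard error 0.562, limma, adjusted p = 2.22e-05), Il1b by 6.64 (standard error 1.67, adjusted p = 0.00362) and Fos by 3.25 (standard error 0.935, adjusted p = 0.00767). Agtr1a (-4.38), Ace (-3.60), Jun (-4.96) and Rgs4 (-4.50) were lower, with adjusted p of at most 0.000128, and so was Dbh (-4.04, adjusted p = 0.0151). Without rat 4600, 5 genes passed, namely Ace, Agtr1a, Alox5ap, Jun and Rgs4. An exact permutation test called 0 genes, with 0.0476 as the smallest p it can give before adjustment. Between the Sham groups, SHR had 1 rat and no spread of its own, and an exact permutation test of 1 against 3 rats cannot go below p = 0.250. Only if this rat is assumed to vary like the rats of the other groups did limma give an adjusted p under 0.05, for 4 genes. Alox5ap was higher in this rat by 4.48 (standard error 0.776, adjusted p = 0.000379). Jun (-5.73, standard error 1.22, adjusted p = 0.00180), Ace (-3.91, standard error 0.865, adjusted p = 0.00180) and Agtr1a (-4.13, standard error 0.972, adjusted p = 0.00244) were lower. Il10 had -3.01 (standard error 1.28, adjusted p = 0.118).

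The control procedures were compared with each other to see whether a scrambled oligonucleotide alone differed from surgery. In WKY, Il1a was at -5.30 ± 2.39 (SD, n = 5) after Scrambled and at -1.23 ± 1.10 (SD, n = 3) after Sham, and this difference of -4.07 (standard error 1.24) did not pass (limma, adjusted p = 0.0811). Ace had -1.16 (standard error 0.547), Actb 0.86 (standard error 0.465) and Rgs4 1.29 (standard error 0.712), each with an adjusted p of 0.278. Limma and the exact permutation test both called 0 genes, and 2 (Il1a and Ace) had an unadjusted p under 0.05 in limma. Il1a passed without rat 4615, in 4 of 16 other settings, and when p-values were adjusted over its list alone. In SHR, 2 Scrambled rats stood against 1 Sham rat that is assumed to vary like the others. Ptgs2, with a value in 1 rat of each group, differed by 3.55 between Scrambled and Sham (standard error 1.49, limma, adjusted p = 0.568). Fos differed by 2.72 (standard error 1.37, adjusted p = 0.596), Rgs4 by -1.59, Il1b by 2.97 and Il10 by 1.33, the last 3 each with an adjusted p of 0.774. Limma called 0 genes, and 1 (Ptgs2) had an unadjusted p under 0.05. Without rat 4600, which leaves 1 rat on each side, the Fos difference was 0.45 and that of Il1b 0.28. Those of Rgs4 (-2.06) and Il10 (1.70) were then larger.

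Cocktail was also set against Sham, the procedure with no oligonucleotide. In WKY, Rgs4 was at 2.70 ± 0.93 (SD, n = 4) after Cocktail and at 1.20 ± 1.83 (SD, n = 3) after Sham (limma, standard error of the difference 0.745, adjusted p = 0.631). Without Sham rat 4611, this difference was 0.49, that of Ptgs2 -0.48, and that of Rgs4 between Scrambled and Sham 0.28. Il1a had a log2 fold change of -2.26 (standard error 1.30) with the same adjusted p. Ptgs2 had -1.16 (standard error 0.802) and Th had 1.71 (standard error 1.28), each with an adjusted p of 0.704. In SHR, Agtr1a had 1.61 (standard error 0.922), Dbh 2.48 (standard error 1.71), EiF4e 0.63 (standard error 0.661), Jun 1.04 (standard error 1.16) and Il10 0.93 (standard error 1.22), each with an adjusted p of 0.999. Ptgs2, which was lower after Cocktail than after Scrambled in SHR, differed from the Sham rat by -0.49, with a 95% confidence interval from -2.99 to 2.01. Limma called 0 of 19 genes in either strain, and 0 had an unadjusted p under 0.05. In WKY, the exact permutation test called 0 genes. In SHR, the only Sham rat is assumed to vary like the rats of the other groups.

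Values were missing for 160 of 2071 gene and section pairs (7.73%), most often for Il1b (40.4% of sections), Ptgs2 (27.5%), Agtr1a (15.6%) and Dbh (11.9%). For these 4 genes, none of 12 exact permutation tests of rats on the share of sections without a value passed (smallest adjusted p = 0.762), although the 4 tests of SHR Cocktail against Scrambled cannot go below p = 0.0476 before adjustment and so could hardly pass. For Ptgs2 this share averaged 36.7% over the SHR Cocktail rats and 53.6% over the SHR Scrambled rats, and for Agtr1a 2.22% and 28.6%. In the Scrambled averages the 1 section of rat 4604 weighs as much as the 14 of rat 4600. Counted by sections, Ptgs2 goes the other way, with a value in 70.6% of SHR Cocktail and 86.7% of SHR Scrambled sections. Agtr1a had a value in 94.1% and 46.7%.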

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

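The counts of divided rats below were planned; the tests of the strain difference, of rat 4600 and of rat 4614 were chosen after the results had been seen. For rat 4614 the comparison with parted sections, and for rat 4600 the separate reading of Il1a, were added after the first values were known.

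Within groups of 4 or 5 rats, 1 rat stood apart by Dixon's test in 2 of 57 gene and group sets, where chance gives 2.85. Dbh in SHR Cocktail was at -5.49 in rat 4595 and between -2.63 and -1.78 in the other 4 rats. EiF4e in WKY Scrambled was at 4.08 in rat 4614 and between 2.42 and 2.77 in the other 4 rats.

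The same rats were divided in other ways into groups of the same sizes. Of 100 divisions drawn for SHR against WKY under Cocktail, only 1, the real one, gave 7 genes, and the highest other count was 6. Over the control procedures, 1 of 84 divisions, the real one, gave 9 genes, with 5 as the highest other count. Chance can be excluded for both counts at a share of 0.05. Where the real count was 0, the divisions say nothing about chance, since every one gives at least 0. This holds for the 100 divisions of WKY Cocktail and Scrambled (highest count 1), the 56 of WKY Scrambled and Sham (highest 3) and the 35 of WKY Cocktail and Sham (highest 0).

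The strain difference in Ace, Agtr1a, Alox5ap, Il10, Jun and Rgs4 was weighed against 3 technical explanations. RNA input as the whole cause is argued against by 1 setting. All 6 genes kept call and direction in both strain comparisons with the section median Ct as a covariate. Leaving out the normalised values named as the 9 late WKY sections kept 5 of the 6. Il10 then went from -2.22 to -2.08 under Cocktail (limma, adjusted p = 0.0575). This setting cannot judge RNA input. Most of those names held normalised values of earlier sections of the same rat, so most late values stayed in. Centring on the section median is argued against likewise, since with Actb as the reference 5 of the 6 kept them, and Il10 was at -2.24 (adjusted p = 0.0597); without any normalisation, Alox5ap, Ace (-4.54), Agtr1a (-4.60), Jun (-6.04) and Rgs4 (-3.85) passed over the controls, while under Cocktail Alox5ap alone passed, and Rgs4 went from -2.41 to -0.85 (adjusted p = 0.605), Ace from -3.25 to -1.70 (adjusted p = 0.320), Agtr1a from -3.09 to -1.72 (adjusted p = 0.333), Il10 from -2.22 to -1.51 (adjusted p = 0.413) and Jun from -4.23 to -2.69 (adjusted p = 0.148), where the median over all genes moved by 1.37 and the mean median Ct of the rats was 15.3 in WKY and 13.7 in SHR. A run that differed by strain cannot be told apart from strain, because no run was given. The 2 strains were handled unlike, since 44 WKY and 0 SHR sections were named differently in the 2 tables. The subtracted value was the median of the 19 genes in 1 of 50 WKY and 59 of 59 SHR sections. These names and values alone are argued against as the cause. All 109 normalised sections found their raw section within the same rat. All 6 genes kept call and direction with raw Ct centred on the section median. A difference of the strains themselves, and a strain variant under a primer, may also account for the strain difference and stay untested.

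Rat 4600, which holds 14 of the 15 SHR Scrambled sections, had the highest Il1a (-0.96), Il1b (-0.04), Fos (4.69) and Ptgs2 (-1.15) of all SHR rats (and the lowest Agtr1a, Dbh, Th, Ace, Agtrap, Ptgr1 and Ptgs1), against means of -4.93 ± 1.30 (SD, 7 rats), -5.29 ± 0.82 (SD, 6 rats), -0.01 ± 0.38 (SD, 7 rats) and -5.09 ± 0.69 (SD, 5 rats). Of its sections with a value, 12 of 14, 12 of 13, 13 of 14 and 12 of 13 lay above the highest mean of any other SHR rat. Single sections of the other rats were not held against that mean. Low RNA input is argued against, as its mean section median Ct of 14.8 lay within the 11.9 to 15.9 of the other SHR rats. Centring on the section median is argued against for Il1b, Fos and Ptgs2, whose raw Ct was earlier than in the other SHR rats by at least 2.36 of their standard deviations; for Il1a the lead of 1.85 leaves it open. A state of this rat, such as tissue reaction to the surgery, may account for it. Whether it is tied to the Scrambled oligonucleotide cannot be told. Rat 4604 was at 0.15 for Fos and -5.48 for Il1a, but it has 1 section. The lowest single sections of rat 4600 were at -1.05 for Fos and -5.92 for Il1a.

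The number 4614 was given to 5 WKY Cocktail and 2 WKY Scrambled sections. The distance between the 2 mean profiles over 18 genes was 9.52, which ranked 20 of the 20 pairs of a Cocktail and a Scrambled WKY rat (median 6.09, SD 2.02). Parting 2 sections from the rest of either WKY rat with at least 7 sections gave as large a distance in 1 of 57 ways. These partings cannot decide whether sections of 1 rat were listed under both procedures. They overlap and come from 2 other rats. The 2 Scrambled sections were also near-identical (standard deviation over genes of 0.312, against a median of 1.52 over pairs from 1 rat). Their mean is thus closer to 1 section than that of most parted pairs. A mistyped number in either group may be the source. Leaving out both sets changed no count of genes, although Agtrap then no longer passed under Cocktail.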

How the results depend on the processing

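Leaving out late sections, Actb as the reference and the section median Ct as a covariate were chosen after the data had been seen; all other alternatives were planned. Direction held in all but 5 of the 1463 gene values under other settings, while 90 lost and 54 gained a call. This count says little about direction, since part of it is fixed in advance. The exact test, the fits of the compared groups alone and the filters on genes and sections leave the log2 fold change as it was. Settings that touch only WKY sections leave the comparisons within SHR as they were. Apart from leaving out each rat, Ace, Agtr1a, Alox5ap, Jun and Rgs4 passed between the strains under Cocktail and over the control procedures in all alternatives, except that Agtr1a was not tested under the filter on genes and that Alox5ap alone passed under Cocktail with no normalisation. SHR Cocktail against Scrambled was the least stable, with 2 genes as reported. The cause was not tested unless given. It gave 1 gene with raw Ct centred on the section median (Agtr1a), with missing values at the lowest value (Agtr1a), without rats of 1 section (Fos) and without late sections (Ptgs2). It gave 0 with no normalisation, with Actb as the reference, with the Ct covariate, with the compared groups alone, with the exact test (whose smallest p is too large for 5 against 2 rats) and with 15 genes past the filter (which removes Agtr1a and Ptgs2). Adjusted p for Agtr1a ranged from 0.0015 to 0.452 over the alternatives other than leaving out each rat in turn.

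With no normalisation, SHR against WKY gave 1 gene under Cocktail, 5 under Scrambled and 1 under Sham, and WKY Scrambled against Sham gave 1. The median over genes then moved by -1.36 to 1.61 against the main values, by -0.86 to 0.57 with Actb, and by -0.30 to 0.29 with raw centring. Higher and lower calls under Cocktail, 2 and 5 as reported, were 1 and 5 with raw centring and 1 and 0 with no normalisation. Under Scrambled, 3 and 5 became 1 and 4, under Sham 1 and 3 became 0 and 1, and over the controls 3 and 6 became 1 and 5, all with no normalisation. SHR Cocktail against Scrambled had 1 and 1 as reported, and 1 and 0 with raw centring. Reversed values with no normalisation were Actb (-0.48) and Rgs4 (-0.0434) in WKY Scrambled against Sham and Rgs4 (-0.0023) in WKY Cocktail against Sham. The Ptgs2 strain by treatment difference was 0.62 with missing values at the lowest value. Actb as the reference gave 1 gene in WKY Scrambled against Sham, the filter on genes 5 in SHR against WKY Scrambled, where the exact test gave 0, and medians 1 in the strain by treatment test. Without rats of 1 section, the strain by treatment test and SHR Scrambled against Sham gave 1 each.

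Weighting rats by their number of sections, or fitting the sections, gave more genes in most comparisons. The count stayed at 0 in WKY Cocktail against Scrambled and SHR Cocktail against Sham. Of these settings, only independent sections take no account of the rat. In the order SHR Cocktail against Scrambled, strain by treatment, SHR against WKY Scrambled, SHR Scrambled against Sham and SHR against WKY Sham (2, 0, 8, 0 and 4 as reported), weights by sections gave 9, 4, 14, 8 and 8, and independent sections 9, 6, 15, 12 and 9. The rat as a random block gave 8, 4, 12, 3 and 7. The section number as a block with the rat as a random block gave 9, 4, 13, 5 and 8. WKY Scrambled against Sham gave 2 with independent sections and with either block, and WKY Cocktail against Sham 1 with independent sections and with the number block. Sections of the same number did not deviate together (median r per pair of groups from -0.35 to 0.33), so the number does not pair them.

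Leaving out each rat in turn, except SHR Sham rat 4596, the only one of its group, gave 0 to 5 genes in SHR Cocktail against Scrambled (0 without SHR Cocktail rats 1694, 1696, 4598 or 4602 or Scrambled rat 4600, 5 without rat 4604), 0 to 2 for strain by treatment, 5 to 8 for the strains under Cocktail, 5 to 10 under Scrambled, 5 to 9 over the controls (5 without rat 4600 in both), 4 under Sham, 0 to 1 in WKY Scrambled against Sham, 0 to 1 in SHR Scrambled against Sham and 0 elsewhere. The Fos strain by treatment difference then ran from -4.51 to 0.0315, reversed without rat 4600. Profile distances ran from 2.43 to 3.97 in WKY and from 5.19 to 10.2 in SHR. The filter on sections removed none of the 109 and tests nothing. The exact test cannot go below p = 0.167, 0.250 or 0.333 for the groups of 1 rat, and it was not run for the strain by treatment test or the mean of controls. SHR Scrambled and Sham rest on 2 rats and 1 rat, and Il1b and Ptgs2 on fewer sections than the other genes.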

Other observations

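The hypotheses on Dbh with Th and on a return of SHR values towards WKY were written before their results were seen; the others are values with no test of cause.

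Between sections of the same rat, the catecholamine genes varied together. Dbh and Th, which act in the same noradrenergic neurons, had a correlation of r = 0.666 (rho = 0.651) over 90 sections of 17 rats after each rat's mean was taken out. The permutation p within rats was 1e-05, the smallest that 100000 permutations can give, and 5e-05 after adjustment over 5 gene pairs. Without the 2 sections farthest from the median, r was 0.612. It stood at the 98.8th percentile of all 171 gene pairs, whose median r was 0.06. This is consistent with sections that hold different amounts of catecholamine-synthesizing tissue (r = 0.666).

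Among the other 4 pairs, the cyclooxygenase genes Ptgs1 and Ptgs2 had r = 0.347 (rho = 0.414, 77 sections, adjusted permutation p = 0.0130) and r = 0.338 without the 2 farthest sections. The cytokine genes Il1a and Il1b had r = 0.370 (rho = 0.442, 61 sections, adjusted permutation p = 0.0433) and r = 0.335 without them. Among all gene pairs, the r of Ptgs1 with Ptgs2 stood at percentile 84.2 and that of Il1a with Il1b at percentile 83.6. Neither pair thus stood out from the other gene pairs as Dbh with Th did. Ace and Agtr1a (r = 0.213, rho = 0.145, adjusted permutation p = 0.152) and Fos and Jun (r = 0.144, rho = 0.0936, adjusted permutation p = 0.326) did not pass. The share of the variance of a gene that lay between rats of a group had a median of 10.3% over the 19 genes and exceeded the share within rats for 0 genes.

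It was asked whether Cocktail moves SHR values towards those of WKY. Ptgs2 and Il1b lacked a value in some SHR rats and were left out. Across the other 17 genes, the Cocktail effect in SHR and the strain difference of the Sham rats had r = -0.265 (rho = -0.368). Genes are not independent replicates here, and 8 genes had opposite signs. Of the 21 ways to divide the SHR rats, 4 gave an r as low (one-sided exact permutation p = 0.190, the smallest possible being 0.0476). With 2 Scrambled rats and 1 SHR Sham rat, neither a return towards WKY nor its absence can be read from this.

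Pairs of sections from the same rat were compared for near-identical values. The closest, a pair of SHR Sham sections, differed with a standard deviation over genes of 0.127 and a pair of SHR Cocktail sections with 0.159, against a median of 1.52 over 591 such pairs. In the comparisons of groups each rat counts once, so repeated measurement of a section would not change n there. The correlations of gene pairs count sections, so repeats would raise their number of sections.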
